A study of Homo sapiens with 9 samples.

How the data were processed

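RNA sequencing of the human renal carcinoma cell line ACHN was deposited for 9 libraries in 3 groups of 3. The groups received 0.1% DMSO, 25 nM piericidin A or 50 nM piericidin A, an inhibitor of respiratory complex I. Whether the piericidin A groups also held DMSO is not stated in the labels. The labels do not say whether the 3 samples of a group were separate cultures, so the p-values of single genes and of permutation tests measure the spread between these samples. The length of treatment, the RNA selection and the strandedness of the libraries were not given in the sources used here.

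The deposited table that is named for read counts holds FPKM for 30673 Ensembl genes, each above 0 in at least 1 library, and no raw counts. The second deposited table holds log2 FPKM with no pseudocount for the 18859 genes above 0 in all 9 libraries. Its values equal the log2 of the FPKM table to within 0.005, and it adds symbol, position, length and type of each gene. The authors mapped to hg38 per the submitters' processing notes, and positions are those of the authors' table. The aligner, the counting program and the annotation release were not given in the sources used here. Symbols came from the log2 table for 18859 genes and from the reference names for 11237 further genes, which left 577 without a symbol.

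For each library, deposited FPKM times gene length was a whole multiple of a single step for 100% of the 18859 genes with a length, within a tolerance of 0.01. Dividing by that step recovered whole fragments, 24365472 to 29245674 per library, and the same step on simulated fragments recovered 100%. These fragments served for depth, for shares of fragments, for CPM and for alternative scalings. The deposited FPKM already carried a scaling for composition: median-of-ratios factors computed from the deposited FPKM were 1.0041 in every library.

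The plan written before the data were examined assumed raw counts and a quasi-likelihood test for counts. Since the values are FPKM, the main test was changed to limma (lmFit and eBayes with trend and robust) on log2(FPKM + 0.1). The fit used all 9 libraries with group as the only covariate. Genes with at least 0.5 FPKM in at least 3 libraries were tested, 15541 in all. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was counted as changed at an adjusted p under 0.05. The pseudocount shrinks the log2 fold changes of genes near 0 FPKM. A log2 fold change is given with the standard error (SE) of the limma fit, and levels are given as mean ± SD with n = 3. Where a gene list is described, a value in brackets after a gene is its log2 fold change.

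The 37 gene lists (1005 members) were written before the data were examined and were tested with camera in limma on the same values, at a preset correlation of 0.01, for lists with at least 5 tested members. Camera p-values were adjusted over the lists within a comparison. For each list the number of members changed is given after adjustment over all genes and, in brackets, after adjustment over the list alone. Genes were named by a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM and no overlap between the groups' libraries, leaving out genes without a symbol, clone-based names, antisense and intergenic non-coding genes, small RNAs and pseudogenes. It adds up to 4 members with the smallest p of each list described, with 1 member of the other direction where those 4 go 1 way. A list was described if camera called it or at least 20% of its tested members changed. The rule further names PRDX1 and the 7 complex I subunits of the mitochondrial genome. Genes named for any other reason are said to be so. Of the 341 genes the rule picked, 135 overlap another gene of the authors' annotation, 45 of them on the same strand. The strandedness of the libraries is not given, so reads of the other gene may be counted in any of these, and the report states the overlap only for the largest changes and some further genes.

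Shares of fragments and numbers of genes were compared by exact two-sided permutation tests over the 20 splits of 6 libraries, whose smallest p is 0.1. The likeness of the 2 doses was compared with 50 simulations in which unchanged groups shared the 3 DMSO libraries. The fit was tested on simulated data with 200 changed genes. The noise was independent between genes and far fewer genes changed than were called in the data, so the shares recovered and falsely called need not hold there. In the 25 nM against DMSO simulation of 15541 genes it recovered 49.3%, 86.6% and 93.9% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.97% false calls. In the 50 nM against DMSO simulation those shares were 52.2%, 73.1% and 95.5% with 7.55% false calls. In the 50 nM against 25 nM simulation they were 56.7%, 71.6% and 87.9% with 3.36% false calls. Camera called 5 of 5 shifted simulated sets and 0 of 5 unshifted ones. The genes of these sets were simulated independently, so this result cannot speak for lists whose members move together. In the proteins of the mitochondrial genome the estimated correlation was 0.875.

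For 5 lists of short genes, each member's log2 fold change was also set against that of genes of like length. The median of the 50 protein-coding genes outside these lists nearest in length was used, with 2000 bootstrap resamples of the members. This step was added after the values were seen, and the other lists were not matched for length. Bootstrap intervals and the interval and p-value of an odds ratio cover the spread between genes taken as independent, and not the spread between libraries. Camera p-values at the preset correlation set the genes of a list against the other tested genes and take them as nearly independent.

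Alternatives covered scaling, the filter, the pseudocount, the test (limma-voom on the recovered fragments), the deposited log2 values, a replicate block, the groups in the fit, mitochondrially encoded genes, the gene types and each library left out in turn. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.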

Results

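Piericidin A at 25 or 50 nM changed the transcriptome of ACHN cells, a human renal carcinoma line, with the largest rises in inducible chaperones and broad falls in targets of hypoxia-inducible factor (HIF). The series examined how this complex I inhibitor acts on renal carcinoma cells by sequencing RNA from 3 libraries each of 0.1% DMSO, 25 nM and 50 nM cells. Recovered fragments numbered 27394108, 26806226 and 29245674 in the DMSO libraries. They numbered 25006484, 26316327 and 25205782 at 25 nM, and 24365472, 24888311 and 26395689 at 50 nM. The first principal component held 47% of the variance and ordered the groups by dose, and the second held 13.8%.

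**Figure D1:**
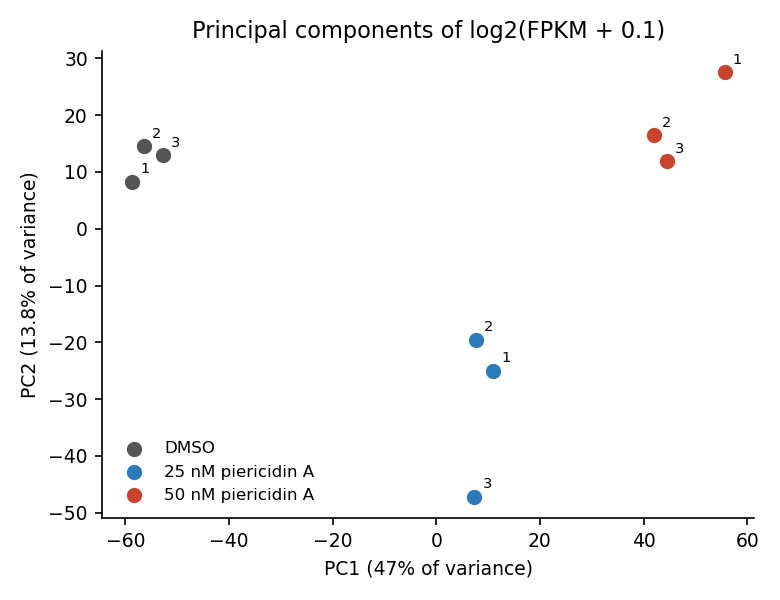
Principal components of log2(FPKM + 0.1), PC1 (47% of variance) against PC2 (13.8%), 1 point per library, coloured by group. On PC1 the DMSO libraries lie between -58.71 and -52.78, the 25 nM libraries between 7.28 and 10.94 and the 50 nM libraries between 41.93 and 55.62.

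Mitochondrially encoded genes held 2.53 ± 0.185% of recovered fragments in DMSO, 4.36 ± 0.669% at 25 nM and 5.93 ± 0.835% at 50 nM (SD, n = 3), with an exact permutation p of 0.1 for each pair of groups. Their messenger RNAs rose from 1.59% to 2.54% and 4.09%, and their ribosomal RNAs from 0.94% to 1.81% and 1.82%. Genes for cytosolic ribosomal proteins held 6.70 ± 0.052%, 8.38 ± 0.687% and 7.75 ± 0.306% of fragments. The 10 most abundant genes held 5.19%, 6.86% and 7.57%. The number of genes above 0 was 23939 ± 291 in DMSO, 24324 ± 355 at 25 nM (exact permutation p = 0.3) and 25936 ± 453 at 50 nM (exact permutation p = 0.1 against either group). Among replicates, the chi-square per degree of freedom of the fragments was 1.79 to 2.50 in DMSO, where counting error alone gives 1. It was 2.48 between the first 2 libraries of 25 nM, 17.2 and 19.6 between those and replicate 3, and 5.09 to 8.49 at 50 nM.

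The comparison of 25 nM with DMSO asked which transcripts respond to the lower dose. Inducible HSP70 genes rose most. HSPA6 (ENSG00000173110, chromosome 1, 161524540-161526910), which is nearly silent in unstressed cells, went from 0.344 ± 0.125 to 28.5 ± 4.08 FPKM (log2 fold change 6.04, SE 0.20, adjusted p = 6.54e-07). HSPA1A (ENSG00000204389, chromosome 6, 31815464-31817946) went from 1.03 ± 0.200 to 38.0 ± 4.57 FPKM (log2 fold change 5.08, SE 0.13, adjusted p = 1.33e-07) and HSPA1B (ENSG00000204388, chromosome 6, 31827735-31830255) from 3.67 ± 0.674 to 146 ± 20.5 FPKM (log2 fold change 5.28, SE 0.14, adjusted p = 1.46e-07), although these near-identical copies share reads and their separate values are uncertain. The co-chaperone DNAJB1 (ENSG00000132002, chromosome 19, 14514770-14529770) went from 14.5 ± 0.871 to 186 ± 25.0 FPKM (log2 fold change 3.66, SE 0.09, adjusted p = 1.33e-07), and HSP90AA1 (ENSG00000080824, chromosome 14, 102080738-102139699), the inducible HSP90, from 152 ± 1.17 to 473 ± 17.3 FPKM (log2 fold change 1.63, SE 0.05, adjusted p = 2.85e-07). The immediate early factor FOS (ENSG00000170345, chromosome 14, 75278774-75282230) fell from 7.01 ± 3.62 to 0.488 ± 0.145 FPKM (log2 fold change -3.51, SE 0.39, adjusted p = 1.54e-04).

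At 25 nM, 8086 of 15541 tested genes changed against DMSO, 4084 higher and 4002 lower, against 3799 and 4261 when libraries were scaled by fragment totals. Of these, 580 were at least 2-fold higher and 259 at least 2-fold lower, 112 and 158 of them protein-coding. In 9729 genes (62.6%) the 3 libraries of 1 group lay entirely above the other 3, where chance gives 10%. The other large rises were those of ID3 (2.97), HSPE1 (2.01), HIST1H4E (1.86), GADD45G (1.73) and BRICD5 (1.62). The strandedness of the libraries is not given, DNAJB1, HSPE1 and BRICD5 overlap TECR, HSPD1 and MLST8, and histone genes share reads with near-identical copies, so these values are uncertain. The other large falls were in the methionine adenosyltransferase MAT2A (-1.97, overlapping GGCX), the cholesterol exporter ABCA1 (-1.80), the p53 target BTG2 (-1.74), ZBED6 (-1.65, inside ZC3H11A) and ETAA1 (-1.60), CDH1 (-1.60), RHOB (-1.58), ARRDC3 (-1.54) and LCN2 (-1.53). ABCA1, CDH1, ARRDC3 and HSP90AA1 also overlap other genes. The fall in ZBED6 was not called without DMSO replicate 2 or without DMSO replicate 3, and its log2 fold change was -0.98 without the 25 nM replicate 3.

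**Figure D2:**
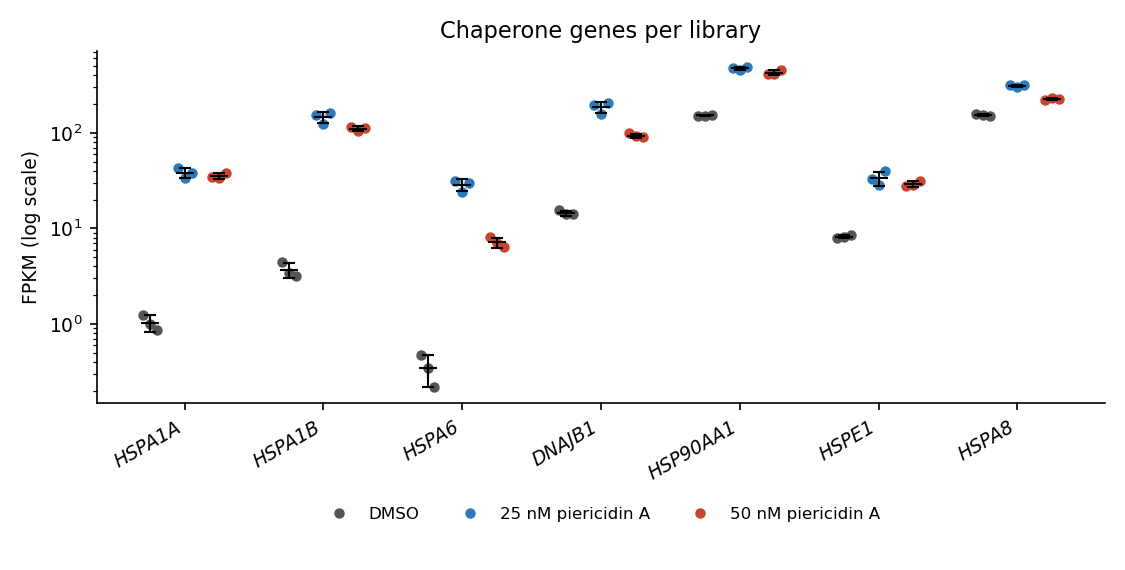
FPKM (log scale) of 7 chaperone genes in each library, with points for libraries and bars for the mean and SD (n = 3). DNAJB1 averages 14.5 FPKM in DMSO, 186 at 25 nM and 93.7 at 50 nM.

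Of the 19 tested heat shock genes of the cytosol, 15 rose and 1 fell (17 adjusted over the list alone), with a median log2 fold change of 0.77, camera adjusted p = 3.99e-07, adjusted p = 0.324 with an estimated correlation. HSPB8 (-0.21) was the member that fell. Many nuclear genes of the respiratory chain rose. Of 35 complex I subunits, 29 rose and 0 fell (29 adjusted over the list alone), with a median log2 fold change of 0.44, camera adjusted p = 6.88e-08, adjusted p = 0.383 with an estimated correlation. NDUFS3 (0.59), NDUFS6 (0.74) and NDUFB2 (0.69) were among them, of which NDUFS3 and NDUFB2 overlap other genes. Of 25 subunits of complexes II to IV and cytochrome c, 21 rose and 0 fell (21 adjusted over the list alone), with a median log2 fold change of 0.39, camera adjusted p = 3.62e-06, adjusted p = 0.383 with an estimated correlation. CYCS (0.64), UQCRB (0.52), UQCR10 (0.58) and COX8A (0.71) were among them. Of 15 ATP synthase subunits, 15 rose and 0 fell (15 adjusted over the list alone), with a median log2 fold change of 0.45, camera adjusted p = 2.13e-05, adjusted p = 0.383 with an estimated correlation. ATP5G1 (0.70), ATP5E (0.56) and ATP5G3 (0.41) were among them. Of 73 mitochondrial ribosomal proteins, 51 rose and 1 fell (57 adjusted over the list alone), with a median log2 fold change of 0.32, camera adjusted p = 6.88e-08, adjusted p = 0.383 with an estimated correlation. MRPL47 (0.46), MRPL18 (0.77) and MRPS15 (0.60) were among them, while MRPS17 (-0.65) fell. Of 75 cytosolic ribosomal proteins, 73 rose and 0 fell (73 adjusted over the list alone), with a median log2 fold change of 0.39, camera adjusted p = 1.95e-13, adjusted p = 0.383 with an estimated correlation. The shares of fragments in cytosolic ribosomal proteins at 25 nM were 8.09%, 7.88% and 9.16% in replicates 1 to 3. Short coding genes as a whole stood higher at 25 nM: across 11709 coding genes the log2 fold change and gene length had a Spearman correlation of -0.369, with a median of 0.19 in the shortest 25% and -0.22 in the longest 25%. The sum of FPKM, 252301 ± 3062 in DMSO and 290176 ± 17322 at 25 nM, was highest in the 25 nM replicate 3, at 310119. Set against the 50 other coding genes nearest in length, a check chosen after the values were seen, the median excess was 0.27 in complex I (95% bootstrap interval 0.14 to 0.39) and 0.27 in cytosolic ribosomal proteins (0.25 to 0.32). It was 0.23 in complexes II to IV (0.17 to 0.38), 0.42 in ATP synthase (0.26 to 0.60) and 0.19 in mitochondrial ribosomal proteins (0.09 to 0.23). In the 13 proteins of the mitochondrial genome, 5 rose and 1 fell (6 adjusted over the list alone), and camera made no call (camera adjusted p = 0.0958, adjusted p = 0.647 with an estimated correlation). Among its complex I subunits, MT-ND4 (1.04), MT-ND4L (0.89) and MT-ND6 (0.48, not called under some alternatives) rose and MT-ND3 (-0.73) fell, and MT-ND1 (-0.09), MT-ND2 (0.21) and MT-ND5 (0.21) were not called. MT-ND4 and MT-ND4L overlap.

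Most HIF targets outside glycolysis fell at 25 nM. Of 23 targets, 1 rose and 18 fell (19 adjusted over the list alone), with a median log2 fold change of -0.55, camera adjusted p = 4e-07, adjusted p = 0.383 with an estimated correlation. CA12 (-0.99), INSIG2 (-0.64), EGLN1 (-0.79) and VEGFA (-0.71) had the smallest p. Of 21 glycolysis genes, 4 rose and 10 fell (15 adjusted over the list alone), with no camera call (camera adjusted p = 0.0769, adjusted p = 0.529 with an estimated correlation). Hexokinase HK2 (-1.29) fell and LDHB (0.32) rose. Of 21 YAP and TEAD targets, 3 rose and 16 fell (20 adjusted over the list alone), with a median log2 fold change of -0.33, camera adjusted p = 0.00212, adjusted p = 0.383 with an estimated correlation. AJUBA (-0.49) and CTGF (-0.55) fell, and NUAK2 (0.97) and ANKRD1 (0.84) rose. Of 26 p53 targets, 7 rose and 15 fell (23 adjusted over the list alone), with a median log2 fold change of -0.20, camera adjusted p = 0.0127, adjusted p = 0.358 with an estimated correlation. POLH (-0.89), ZMAT3 (-1.26) and TP53INP1 (-1.0) fell and GADD45A (0.54) rose. Of 27 matrix and TGF-beta targets, 4 rose and 13 fell (18 adjusted over the list alone), with a median log2 fold change of -0.19, camera adjusted p = 0.0149, adjusted p = 0.383 with an estimated correlation. PMEPA1 (-0.87) was among those that fell. Of 22 regulators of mitochondrial biogenesis and AMP-activated kinase subunits, 2 rose and 11 fell (14 adjusted over the list alone), with a median log2 fold change of -0.20, camera adjusted p = 0.0462, adjusted p = 0.383 with an estimated correlation. FNIP1 (-1.02) and PRKAG2 (-0.59) were among them. The longest 25% of coding genes had a median of -0.22 at 25 nM. The lists that fell were not set against genes of like length, so how far gene length bears on falls of this size was not tested.

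PRDX1, a peroxiredoxin gene, rose from 151 ± 4.99 to 207 ± 14.6 FPKM (log2 fold change 0.45, SE 0.06, adjusted p = 3.88e-04). Of 24 antioxidant enzymes, 18 rose and 1 fell (20 adjusted over the list alone), with a median log2 fold change of 0.36, camera adjusted p = 1.51e-04, adjusted p = 0.383 with an estimated correlation, and SOD2 (-0.75) was the member that fell. Of 20 NRF2 targets, 12 rose and 2 fell (14 adjusted over the list alone, camera adjusted p = 0.0127, adjusted p = 0.383 with an estimated correlation). NQO1 (0.51) and GCLM (0.41) rose. Of 20 aminoacyl-tRNA synthetases, 15 rose and 0 fell (15 adjusted over the list alone, camera adjusted p = 9.85e-05, adjusted p = 0.383 with an estimated correlation). YARS (0.63) and GARS (0.41) rose. Of 41 mitosis genes, 26 rose and 2 fell (29 adjusted over the list alone, camera adjusted p = 5.36e-04, adjusted p = 0.383 with an estimated correlation). PTTG1 (0.69) rose and ASPM (-0.95) fell. Of 39 DNA replication genes, 19 rose and 2 fell (22 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.383 with an estimated correlation). CDC45 (0.60) had the smallest p. Of 13 replication-dependent histones, 6 rose and 0 fell (6 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.383 with an estimated correlation). Of 16 mitochondrial chaperones and proteases, 10 rose and 2 fell (13 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.383 with an estimated correlation). HSPD1 (0.53) rose. Of 35 ribosome biogenesis and MYC targets, 19 rose and 5 fell (25 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.383 with an estimated correlation). BOP1 (0.81) rose and ODC1 (-0.85) fell. Of 24 cholesterol genes, 14 rose and 3 fell (19 adjusted over the list alone, camera adjusted p = 0.0220, adjusted p = 0.383 with an estimated correlation). Of 19 tricarboxylic acid cycle genes, 9 rose and 0 fell (8 adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.383 with an estimated correlation). IDH3B (0.67) and IDH3G (0.52) rose. The shortest 25% of coding genes had a median of 0.19 at 25 nM. How far gene length bears on the rises of PRDX1 and of these lists was not tested.

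Camera called 21 of the 36 lists it could test at 25 nM, 16 up and 5 down, and no camera call of any of the 3 comparisons held with an estimated correlation. In lists without a camera call, single genes moved both ways. Since 8086 of all 15541 tested genes changed, a count of changed members alone marks no list. Stress and inflammatory genes that rose were CXCL3 (1.53), CCL2 (1.09), ASNS (1.07), PSAT1 (0.99), HSPA5 (0.79) and IRF1 (0.81), and SLC38A2 (-1.09), BCL2L11 (-1.20), IER2 (-1.24) and PPARA (-0.89) fell. Of 26 stress response genes, 11 rose and 7 fell (19 adjusted over the list alone). Of 14 serine and one-carbon genes, 6 rose and 2 fell (8 adjusted over the list alone). Of 14 amino acid transporters, 4 rose and 7 fell (11 adjusted over the list alone). Of 26 endoplasmic reticulum chaperones, 12 rose and 4 fell (16 adjusted over the list alone). Of 23 NF-kB targets, 13 rose and 6 fell (19 adjusted over the list alone). Of 20 interferon-stimulated genes, 6 rose and 3 fell (8 adjusted over the list alone). Of 20 fatty acid oxidation genes, 11 rose and 3 fell (14 adjusted over the list alone). Of 14 fatty acid synthesis genes, 4 rose and 5 fell (9 adjusted over the list alone). Of 31 autophagy and lysosome genes, 12 rose and 6 fell (19 adjusted over the list alone). Of 21 apoptosis genes, 5 rose and 10 fell (15 adjusted over the list alone). Of 27 immediate early genes, 6 rose and 12 fell (20 adjusted over the list alone). Of 14 proximal tubule markers, 3 rose and 6 fell (10 adjusted over the list alone). Of 6 endothelial and fibroblast markers, 1 rose and 2 fell (4 adjusted over the list alone). Of 2 leukocyte markers, 0 rose and 0 fell (0 adjusted over the list alone). With 1 library left out at a time, camera no longer called the cycle list or the mitochondrial regulators under some omissions, while 7737 genes changed without the 25 nM replicate 3.

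The comparison of 50 nM with DMSO asked which transcripts respond to the higher dose. HIF targets and glycolysis genes fell broadly. ANGPTL4 (ENSG00000167772, chromosome 19, 8363289-8374373) fell from 269 ± 1.96 to 87.3 ± 7.70 FPKM (log2 fold change -1.62, SE 0.07, adjusted p = 4.85e-07), the collagen cross-linking enzyme LOX (ENSG00000113083, chromosome 5, 122063195-122078285) from 141 ± 2.48 to 43.5 ± 3.29 FPKM (log2 fold change -1.70, SE 0.07, adjusted p = 4.85e-07) and hexokinase HK2 (ENSG00000159399, chromosome 2, 74833981-74893359) from 67.8 ± 1.47 to 17.7 ± 1.06 FPKM (log2 fold change -1.93, SE 0.11, adjusted p = 1.86e-06). The glucose transporter SLC2A1 (ENSG00000117394, chromosome 1, 42925375-42959173) fell from 162 ± 6.06 to 83.7 ± 4.56 FPKM (log2 fold change -0.95, SE 0.05, adjusted p = 1.17e-06). HSPA1A remained high, at 35.3 ± 2.32 FPKM (log2 fold change 4.98, SE 0.13, adjusted p = 1.04e-07), as did HSPA1B (4.89), HSPA6 (4.06) and DNAJB1 (2.68).

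**Figure D3:**
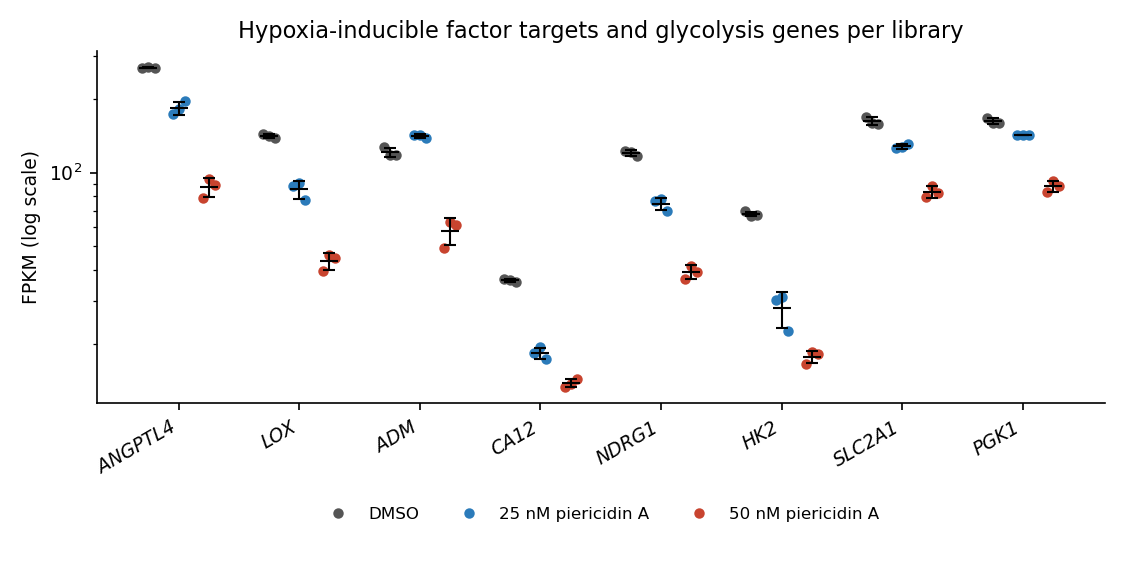
FPKM (log scale) of 5 HIF-responsive genes and 3 glycolysis genes in each library, with points for libraries and bars for the mean and SD (n = 3). ANGPTL4 averages 269 FPKM in DMSO, 184 at 25 nM and 87.3 at 50 nM.

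At 50 nM, 9441 genes changed against DMSO, 4540 higher and 4901 lower, a split that turned to 5295 higher and 4109 lower when libraries were scaled by fragment totals and to 5381 and 4774 with no filter on low values. At least 2-fold changes numbered 1479 up and 277 down, of which 373 and 230 were protein-coding. The groups' libraries did not overlap in 10940 genes (70.4%, where chance gives 10%). The other large rises were those of ID3 (2.59), BRICD5 (2.40), MTG1 (2.30), AMH (2.15), STRADA (2.09) and PILRB (2.04), of which BRICD5, MTG1 and PILRB overlap MLST8, SPRN and PILRA, so their values are uncertain. The other large falls were in FOS (-3.18), the glycogen-targeting subunit PPP1R3C (-2.59), the kinase SGK1 (-1.91), the lipid droplet gene HILPDA (-1.80), and KCTD11 (-2.24), RIMKLA (-1.96), FAM110C (-1.87), SOX9 (-1.79) and ABCA1 (-1.77). ANGPTL4, LOX, HK2, SLC2A1, HILPDA and ABCA1 overlap other genes, so the size of their falls is uncertain too.

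Of 23 HIF targets, 1 rose and 22 fell (23 adjusted over the list alone), with a median log2 fold change of -1.13, camera adjusted p = 1.36e-10, adjusted p = 0.381 with an estimated correlation. INSIG2 (-1.35) and CA12 (-1.39) had the smallest p, and WSB1 (0.82) was the member that rose. Of 21 glycolysis genes, 0 rose and 19 fell (19 adjusted over the list alone), with a median log2 fold change of -0.56, camera adjusted p = 3.03e-07, adjusted p = 0.381 with an estimated correlation. They included PGK1 (-0.88) and PFKFB4 (-0.96), and LDHB (0.04) was not called. Of 21 YAP and TEAD targets, 2 rose and 16 fell (18 adjusted over the list alone), with a median log2 fold change of -0.53, camera adjusted p = 5.05e-04, adjusted p = 0.381 with an estimated correlation. IGFBP3 (-1.37) and CTGF (-0.90) fell. Of 27 matrix genes, 2 rose and 18 fell (20 adjusted over the list alone), with a median log2 fold change of -0.42, camera adjusted p = 5.58e-04, adjusted p = 0.455 with an estimated correlation. LOXL2 (-0.73) fell and COL1A1 (0.71) rose. Of 27 immediate early and MAPK feedback genes, 3 rose and 21 fell (24 adjusted over the list alone), with a median log2 fold change of -0.34, camera adjusted p = 6.51e-04, adjusted p = 0.381 with an estimated correlation. SPRY1 (-1.40) and SPRED1 (-1.10) fell and JUN (0.40) rose. Of 14 fatty acid synthesis genes, 2 rose and 8 fell (10 adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.509 with an estimated correlation), with a fall in the desaturase SCD (-1.54). Of 26 p53 targets, 6 rose and 16 fell (22 adjusted over the list alone, camera adjusted p = 0.0441, adjusted p = 0.381 with an estimated correlation). BTG2 (-1.03) fell and DDB2 (0.47) rose.

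**Figure D4:**
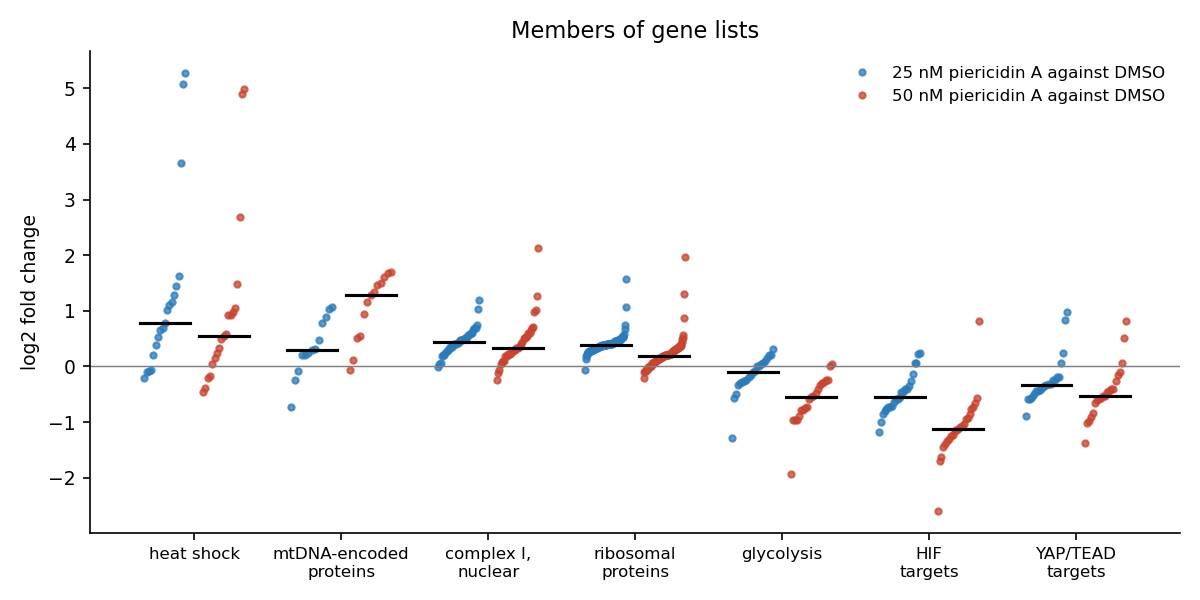
Log2 fold change of each tested member of 7 gene lists, 25 nM and 50 nM each against DMSO, with points for genes and horizontal bars for medians. The median of the HIF targets is -0.55 at 25 nM and -1.13 at 50 nM.

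Messenger RNAs of the mitochondrial genome rose at 50 nM. Of 13 genes, 11 rose and 0 fell (11 adjusted over the list alone), with a median log2 fold change of 1.29, camera adjusted p = 5.54e-04, adjusted p = 0.753 with an estimated correlation. They included MT-CO1 (1.29), MT-CO2 (1.61) and MT-CO3 (1.5), of which MT-CO3 overlaps MT-ATP6. Of the complex I subunits, MT-ND4 (1.70), MT-ND4L (1.67), MT-ND2 (1.16) and MT-ND3 (0.55) rose, MT-ND1 (0.51) rose but not without 50 nM replicate 3 or DMSO replicate 3, and MT-ND5 (0.12) and MT-ND6 (-0.06) were not called. Of 35 nuclear complex I subunits, 25 rose and 1 fell (27 adjusted over the list alone), with a median log2 fold change of 0.34, camera adjusted p = 7.7e-05, adjusted p = 0.704 with an estimated correlation. NDUFS6 (0.71) rose, as did NDUFB2 (0.70) and NDUFV2 (2.12), whose values are uncertain because they overlap other genes. Of 15 ATP synthase subunits, 10 rose and 0 fell (10 adjusted over the list alone, camera adjusted p = 0.00687, adjusted p = 0.806 with an estimated correlation). Of 73 mitochondrial ribosomal proteins, 38 rose and 12 fell (50 adjusted over the list alone, camera adjusted p = 0.00782, adjusted p = 0.806 with an estimated correlation). MRPS5 (0.57) rose and MRPL44 (-0.50) fell. Of 75 cytosolic ribosomal proteins, 39 rose and 1 fell (34 adjusted over the list alone, camera adjusted p = 5e-04, adjusted p = 0.806 with an estimated correlation). The shortest 25% of coding genes had a median of 0.08 and the longest 25% of -0.23. Beside genes of like length the median excess was 0.25 in nuclear complex I (95% bootstrap interval 0.10 to 0.41), 0.32 in ATP synthase (0.20 to 0.67), 0.09 in complexes II to IV (0.01 to 0.25), 0.20 in mitochondrial ribosomal proteins (0.04 to 0.27) and 0.18 in cytosolic ribosomal proteins (0.13 to 0.25). Of 19 heat shock genes, 13 rose and 3 fell (16 adjusted over the list alone), with a median log2 fold change of 0.56, camera adjusted p = 5.21e-04, adjusted p = 0.381 with an estimated correlation, and BAG3 (-0.46) fell. PRDX1 averaged 165 ± 10.1 FPKM and its change was not called (log2 fold change 0.13, SE 0.06, adjusted p = 0.0996).

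Camera called 13 lists at 50 nM, 6 up and 7 down. Since 9441 of all 15541 tested genes changed, a count of changed members alone marks no list. Of 11722 protein-coding genes, 3010 were higher and 4681 lower than in DMSO (median log2 fold change -0.09). Of 2882 genes of non-coding types, 1213 were higher and 210 lower (median 0.48), and the lists were not tested against coding genes alone. In the lists without a call, rises included CXCL3 (1.14), ASNS (0.85), PSAT1 (0.84), TXNIP (0.88) and SPG7 (0.99), and falls included NDRG1 (-1.61), CDH1 (-1.67), SLC38A2 (-1.10), ODC1 (-0.94), MYC (-0.80), TRIB3 (-0.81), MCL1 (-0.75) and SOD2 (-0.87). Of 13 histones, 7 rose and 1 fell (8 adjusted over the list alone). Of 25 subunits of complexes II to IV, 9 rose and 1 fell (9 adjusted over the list alone). Of 24 antioxidant enzymes, 12 rose and 3 fell (15 adjusted over the list alone). Of 20 NRF2 targets, 7 rose and 3 fell (9 adjusted over the list alone). Of 21 apoptosis genes, 3 rose and 11 fell (15 adjusted over the list alone). Of 35 ribosome biogenesis genes, 14 rose and 6 fell (20 adjusted over the list alone). Of 20 aminoacyl-tRNA synthetases, 9 rose and 5 fell (14 adjusted over the list alone). Of 14 proximal tubule markers, 3 rose and 6 fell (9 adjusted over the list alone). Of 22 mitochondrial regulators, 4 rose and 9 fell (14 adjusted over the list alone). Of 16 mitochondrial chaperones, 6 rose and 4 fell (10 adjusted over the list alone). Of 19 tricarboxylic acid cycle genes, 4 rose and 8 fell (12 adjusted over the list alone). Of 14 amino acid transporters, 5 rose and 7 fell (13 adjusted over the list alone). Of 26 endoplasmic reticulum chaperones, 7 rose and 12 fell (19 adjusted over the list alone). Of 23 NF-kB targets, 11 rose and 9 fell (20 adjusted over the list alone). Of 14 serine and one-carbon genes, 5 rose and 4 fell (10 adjusted over the list alone). Of 6 endothelial and fibroblast markers, 1 rose and 4 fell (5 adjusted over the list alone). Of 2 leukocyte markers, 0 rose and 1 fell (1 adjusted over the list alone). Of 26 stress response genes, 9 rose and 9 fell (18 adjusted over the list alone), with a median of 0.02, a mean of -0.06 and a camera direction of down. Of 24 cholesterol genes, 8 rose and 8 fell (16 adjusted over the list alone), with a median of -0.02, a mean of 0.05 and a camera direction of up, and the median was 0.04 under scaling by fragment totals. Of 20 fatty acid oxidation genes, 5 rose and 6 fell (11 adjusted over the list alone), with a median of -0.04, a mean of 0.03 and a camera direction of down, against 7 higher and 4 lower under scaling by totals. Interferon-stimulated genes gave 6 higher and 8 lower of 20 (15 adjusted over the list alone), against 6 and 4 under scaling by totals. Autophagy and lysosome genes gave 8 higher and 12 lower of 31 (21 adjusted over the list alone), against 10 and 9 under scaling by totals. Of 41 mitosis genes, 11 rose and 16 fell (27 adjusted over the list alone), with a median of -0.06 that turned to 0.01 under scaling by totals. Of 39 DNA replication genes, 8 rose and 13 fell (21 adjusted over the list alone), with a median of -0.03 that turned to 0.04 under that scaling. With 1 library left out at a time, camera no longer called p53 targets (adjusted p = 0.0757) or fatty acid synthesis (adjusted p = 0.0849) without the 50 nM replicate 3.

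Genes of non-coding types made up much of the 2-fold rises at 50 nM. Of 2882 tested genes of such types, 789 (27.4%) were at least 2-fold higher than in DMSO and 37 at least 2-fold lower, and 313 (10.9%) were at least 2-fold higher at 25 nM. For 50 nM the share was 50.4% of 230 small RNA genes, 43.3% of 194 sense intronic genes and 32.5% of 832 antisense genes. It was 22.7% of 807 pseudogenes, 12% of 598 long intergenic genes and 3.2% of 11722 protein-coding genes. A single fragment is worth more FPKM on a shorter gene, so short genes near the filter of 0.5 FPKM rest on few fragments. The share of small RNA genes is uncertain for that reason. Of 937 tested genes with no type given, 317 were at least 2-fold higher at 50 nM and 10 at least 2-fold lower. No other gene of this set was called. Types were given only for genes detected in every library, so each of the 937 was undetected in some library. The size of their changes therefore depends on the pseudocount, and their share cannot be set beside those of the genes with a type.

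**Figure D5:**
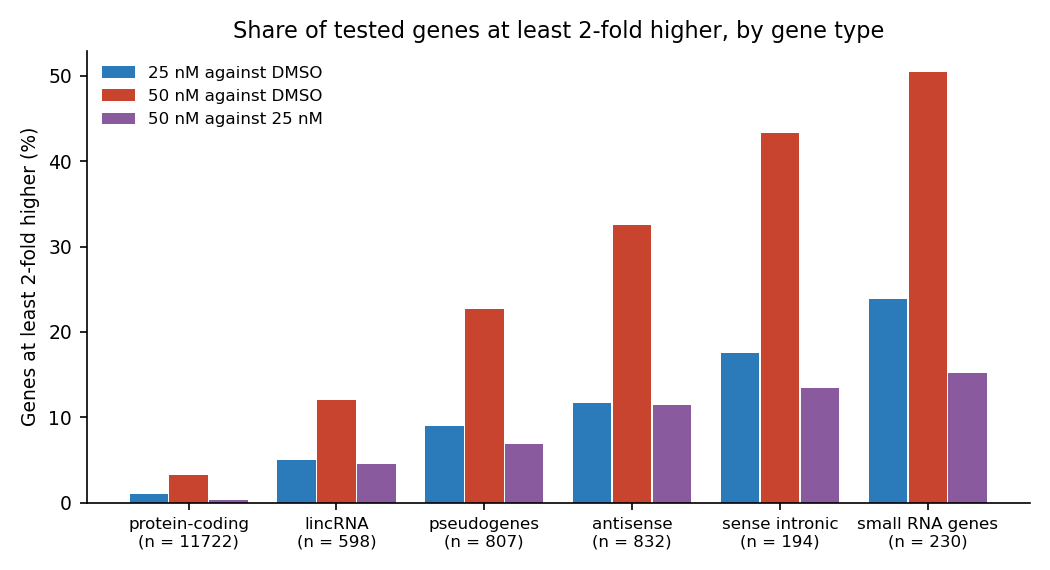
Percentage of tested genes at least 2-fold higher in each of the 3 comparisons, by gene type, with the number of tested genes under each type. Small RNA genes reach 50.4% and protein-coding genes 3.2% at 50 nM against DMSO. Small RNA genes near 0.5 FPKM rest on few fragments.

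The comparison of 50 nM with 25 nM asked what the higher dose adds. Most HIF targets and glycolysis genes stood lower at 50 nM than at 25 nM, as did 10 of 19 heat shock genes, and 10 of 13 messenger RNAs of the mitochondrial genome stood higher. ADM (ENSG00000148926, chromosome 11, 10304680-10307397), which encodes adrenomedullin, fell from 141 ± 2.63 to 57.8 ± 7.31 FPKM (log2 fold change -1.30, SE 0.08, adjusted p = 1.1e-04). HSPA6 fell from 28.5 ± 4.08 to 7.13 ± 0.836 FPKM (log2 fold change -1.98, SE 0.20, adjusted p = 4.11e-04) and DNAJB1 from 186 ± 25.0 to 93.7 ± 4.46 FPKM (log2 fold change -0.98, SE 0.09, adjusted p = 2.82e-04). MT-ND3 (ENSG00000198840, chromosome MT, 10059-10404) rose from 914 ± 192 to 2200.0 ± 292 FPKM (log2 fold change 1.28, SE 0.14, adjusted p = 4.62e-04).

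Between the doses 5205 genes changed, 2288 higher at 50 nM and 2917 lower, a split that turned to 3153 higher and 1358 lower when libraries were scaled by fragment totals. At least 2-fold changes numbered 365 up and 21 down, 34 and 7 of them protein-coding. The libraries did not overlap in 7056 genes (45.4%, where chance gives 10%). The other large rises were those of MT-ATP6 (1.23), MT-CO3 (1.19), SGK494 (1.07), C8orf59 (1.05), STRADA (1.01), IGFN1 (0.98), SPDYE2 (0.97), PILRB (0.97) and RSRP1 (0.96). MT-ATP6 overlaps MT-CO3, SPDYE2 has near-identical copies, and SGK494, C8orf59, IGFN1, PILRB and RSRP1 overlap other genes, so their values are uncertain. The other large falls were those of PPP1R3C (-1.42), ANKRD37 (-1.15), RGS2 (-1.10), ANGPTL4 (-1.07), NOG (-0.97) and LOX (-0.97) and of RIMKLA (-1.0), which was not called in a fit of these 2 groups alone. ANKRD37, ANGPTL4 and LOX overlap other genes, so their values are uncertain too.

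Of 23 HIF targets, 1 rose and 22 fell (23 adjusted over the list alone), with a median log2 fold change of -0.61, camera adjusted p = 1.4e-12, adjusted p = 0.199 with an estimated correlation, and WSB1 (0.76) rose. Of 21 glycolysis genes, 0 rose and 20 fell (21 adjusted over the list alone), with a median log2 fold change of -0.46, camera adjusted p = 1.4e-12, adjusted p = 0.193 with an estimated correlation. PGK1 (-0.70), SLC2A1 (-0.61), GAPDH (-0.61) and HK1 (-0.49) were among them. Of 19 heat shock genes, 0 rose and 10 fell (12 adjusted over the list alone), with a median log2 fold change of -0.28, camera adjusted p = 1.62e-05, adjusted p = 0.193 with an estimated correlation. HSPA8 (-0.45) and BAG3 (-0.38) were among them. Of 26 endoplasmic reticulum chaperones, 0 rose and 16 fell (16 adjusted over the list alone, camera adjusted p = 7.47e-05, adjusted p = 0.193 with an estimated correlation), including P4HB (-0.37) and HSPA5 (-0.30). Of 13 proteins of the mitochondrial genome, 10 rose and 1 fell (11 adjusted over the list alone), with a median log2 fold change of 0.78, camera adjusted p = 1.63e-04, adjusted p = 0.409 with an estimated correlation. Its complex I subunits MT-ND2 (0.95), MT-ND1 (0.60), MT-ND4 (0.66) and MT-ND4L (0.78) rose, MT-ND6 (-0.54) fell and MT-ND5 (-0.09) was not called, and the calls for MT-ND1, MT-ND4, MT-ND4L and MT-ND6 were lost under some alternatives.

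Many cell cycle genes stood lower at 50 nM than at 25 nM. Of 41 mitosis genes, 1 rose and 26 fell (28 adjusted over the list alone), with a median log2 fold change of -0.23, camera adjusted p = 2.99e-08, adjusted p = 0.193 with an estimated correlation. TPX2 (-0.52), HMMR (-0.45), DLGAP5 (-0.41) and CDK1 (-0.34) were among them. Of 39 DNA replication genes, 1 rose and 22 fell (24 adjusted over the list alone), with a median log2 fold change of -0.21, camera adjusted p = 6.53e-06, adjusted p = 0.193 with an estimated correlation. RRM2 (-0.54), RRM1 (-0.48), ORC1 (-0.53) and MCM4 (-0.36) were among them. Of 75 cytosolic ribosomal proteins, 0 rose and 29 fell (33 adjusted over the list alone), with a median log2 fold change of -0.20, camera adjusted p = 1.62e-07, adjusted p = 0.480 with an estimated correlation. Beside genes of like length, where the median was -0.10, the difference in cytosolic ribosomal proteins was -0.10 (95% bootstrap interval -0.13 to -0.09). PRDX1 fell (log2 fold change -0.32, SE 0.06, adjusted p = 0.00498), and of 24 antioxidant enzymes, 0 rose and 9 fell (10 adjusted over the list alone, camera adjusted p = 3.74e-04, adjusted p = 0.428 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases, 0 rose and 14 fell (15 adjusted over the list alone, camera adjusted p = 2.53e-05, adjusted p = 0.280 with an estimated correlation), and of 19 tricarboxylic acid cycle genes, 0 rose and 12 fell (14 adjusted over the list alone, camera adjusted p = 7.47e-05, adjusted p = 0.199 with an estimated correlation). DLAT (-0.31) was among them. Of 25 subunits of complexes II to IV, 0 rose and 8 fell (8 adjusted over the list alone, camera adjusted p = 3.74e-04, adjusted p = 0.480 with an estimated correlation). Beside genes of like length that list differed by -0.10 (95% bootstrap interval -0.15 to -0.08), complex I by -0.02 (-0.06 to 0.02) and ATP synthase by -0.02 (-0.08 to 0.05). Of 21 YAP and TEAD targets, 1 rose and 12 fell (14 adjusted over the list alone, camera adjusted p = 5.33e-04, adjusted p = 0.193 with an estimated correlation). IGFBP3 (-0.78) was among them. Of 27 matrix genes, 1 rose and 11 fell (15 adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.280 with an estimated correlation). Of 23 NF-kB targets, 2 rose and 11 fell (15 adjusted over the list alone, camera adjusted p = 7.76e-04, adjusted p = 0.280 with an estimated correlation). TNFAIP3 (-0.47) fell and TNFAIP2 (0.34) rose. Of 26 stress response genes, 1 rose and 14 fell (15 adjusted over the list alone, camera adjusted p = 0.00422, adjusted p = 0.325 with an estimated correlation). NDRG1 (-0.93) and DDIT4 (-0.82) fell. Of 27 immediate early genes, 1 rose and 13 fell (14 adjusted over the list alone, camera adjusted p = 0.00467, adjusted p = 0.280 with an estimated correlation). DUSP1 (-0.85) fell and IER2 (0.50) rose.

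Camera called 26 lists between the doses, 1 up and 25 down. It sets a list against all other tested genes, which include non-coding types. Of 11722 protein-coding genes, 1542 were higher and 2851 lower between the doses (median log2 fold change -0.06). Of 2882 genes of non-coding types, 668 were higher and 56 lower (median 0.33). The lists were not tested against coding genes alone, so some of the 25 calls may reflect this difference between gene types. Of 24 cholesterol genes, 3 rose and 10 fell (17 adjusted over the list alone, camera adjusted p = 0.00655, adjusted p = 0.199 with an estimated correlation). Of 14 serine and one-carbon genes, 1 rose and 10 fell (11 adjusted over the list alone, camera adjusted p = 0.00846, adjusted p = 0.280 with an estimated correlation). Of 14 fatty acid synthesis genes, 2 rose and 7 fell (9 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.325 with an estimated correlation). SCD (-0.75) was among them. Of 20 fatty acid oxidation genes, 0 rose and 8 fell (8 adjusted over the list alone, camera adjusted p = 0.0431, adjusted p = 0.449 with an estimated correlation). Of 73 mitochondrial ribosomal proteins 5 rose and 23 fell (30 adjusted over the list alone, camera adjusted p = 0.00339, adjusted p = 0.543 with an estimated correlation), a call absent without the 25 nM replicate 3 (adjusted p = 0.339). Their difference from genes of like length was -0.03 (95% bootstrap interval -0.09 to 0.03). Of 16 mitochondrial chaperones 1 rose and 7 fell (8 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.330 with an estimated correlation). HSPD1 (-0.30) fell and SPG7 (0.56) rose. Of 20 interferon-stimulated genes 1 rose and 4 fell (5 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.199 with an estimated correlation), STAT2 (0.48) being the member that rose. Of 31 autophagy and lysosome genes 3 rose and 12 fell (17 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.409 with an estimated correlation), against 6 higher and 3 lower under scaling by totals. Of 20 NRF2 targets 1 rose and 5 fell (6 adjusted over the list alone, camera adjusted p = 0.0337, adjusted p = 0.436 with an estimated correlation), against 1 higher and 0 lower under that scaling. The camera calls for NRF2, autophagy, fatty acid synthesis, fatty acid oxidation and mitochondrial chaperones were lost with some single libraries left out.

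Lists without a camera call between the doses included p53 targets, with 6 higher and 2 lower of 26 (8 adjusted over the list alone), where BTG2 (0.71), MDM2 (0.50) and DDB2 (0.32) rose. Mitochondrial regulators, with 7 higher and 2 lower of 22 (9 adjusted over the list alone), included rises in FLCN (0.50) and PPRC1 (0.39). Of 15 ATP synthase subunits, 0 rose and 4 fell (4 adjusted over the list alone). Of 21 apoptosis genes, 2 rose and 8 fell (10 adjusted over the list alone). Of 13 histones, 1 rose and 1 fell (2 adjusted over the list alone). Of 6 endothelial and fibroblast markers, 1 rose and 2 fell (3 adjusted over the list alone). Of 2 leukocyte markers, 0 rose and 1 fell (1 adjusted over the list alone). Since 5205 of all 15541 tested genes changed, these counts alone mark no list. The median of the apoptosis genes turned from -0.05 to 0.05 under scaling by totals. Under that scaling the majority changed sides in 4 further lists. Nuclear complex I subunits went from 2 higher and 4 lower of 35 (6 adjusted over the list alone) to 3 and 1, and ribosome biogenesis genes from 1 and 7 of 35 (4 adjusted over the list alone) to 5 and 2. Amino acid transporters went from 2 and 5 of 14 (7 adjusted over the list alone) to 2 and 1, and proximal tubule markers from 4 and 6 of 14 (10 adjusted over the list alone) to 5 and 4.

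The changes at 25 nM and at 50 nM were alike. Most heat shock genes rose, most HIF targets fell and FOS, ABCA1 and CDH1 fell at both doses. Of the tested genes, 2968 were higher and 3314 lower at both doses, where independent lists would share 1193 and 1262, and 134 changed in opposite directions. Across the 15541 genes the log2 fold changes correlated at r = 0.785, against a mean of 0.505 in 50 simulations of unchanged groups compared with the same 3 DMSO libraries. Their covariance was 0.399 against 0.0419 in the simulations, and 81.4% of genes had the same sign against 66.6%. When 1 DMSO library was given to 1 dose and the other 2 to the other dose, in each of the 6 ways, r was 0.598 to 0.642, the covariance 0.340 to 0.364 and the genes of the same sign 77.8% to 79.3%. Part of the excess of genes changed at both doses over independent lists may come from the shared DMSO libraries.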

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

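Of the named genes, 18 changed in opposite directions at the 2 doses against DMSO and also differed between the doses (limma, adjusted p under 0.05). The tests of them were planned before the data were examined, but this set was picked by rule after the result was seen.

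HIF and stress genes were among them. ADM, which encodes a vasodilator peptide, averaged 121 FPKM in DMSO, 141 at 25 nM and 57.8 at 50 nM, a log2 fold change of -1.30 between the doses, and its rise at 25 nM (adjusted p = 0.0468 by limma) was lost under some alternatives. The mTORC1 inhibitor gene DDIT4 averaged 240.0, 346 and 196 FPKM in the same order, a change of -0.82 between the doses. The MAPK phosphatase gene DUSP1 averaged 203, 240.0 and 133 FPKM, a change of -0.85. Changes of -0.48 in FOSL1 and -0.47 in TNFAIP3 had the same order of groups.

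The set held 5 proliferation genes, although neither the mitosis list (camera adjusted p = 0.452 by limma) nor the DNA replication list (camera adjusted p = 0.498 by limma) was called at 50 nM against DMSO. Both ribonucleotide reductase subunits were among the 5, RRM1 with a change of -0.48 between the doses and RRM2 with -0.54, RRM2 averaging 37.7, 45.1 and 31.1 FPKM in DMSO, 25 nM and 50 nM. The mitosis genes CDK1 (-0.34), DLGAP5 (-0.41) and TPX2 (-0.52) had the same order.

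Further changes of this kind between the doses were those of DLAT (-0.31), HADHA (-0.37), ME1 (-0.20), MRPS35 (-0.33), MSMO1 (-0.35), PDIA6 (-0.41) and RPSA (-0.40). The calls against DMSO of several of these 18 genes were weak. The rises at 25 nM of DLAT, HADHA, ME1, MSMO1, PDIA6, RPSA and RRM1 and the falls at 50 nM of ME1, MRPS35, RPSA and TNFAIP3 were each lost under at least 1 alternative. ME1 lost its rise under 13 of 20 alternatives and its fall under 13 of 20. MT-ND3 went the other way, averaging 1500.0 FPKM in DMSO, 914 at 25 nM and 2200.0 at 50 nM, a change of 1.28 between the doses.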

How the results depend on the processing

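The alternatives below were planned before the data were examined, except pseudocounts of 1 and 0.01 FPKM, protein-coding genes only and trimmed-mean scaling, which are tests chosen only after the result was seen. The planned count-model Wald test was not run, because the files hold FPKM, and median-of-ratios factors were equal in all libraries and so moved nothing.

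No named gene that was called changed direction, but scaling by fragment totals turned the split into higher and lower genes in each of the 3 comparisons and the majority of members in several lists. Requiring a log2 fold change of at least 1 left 839 genes at 25 nM, 1756 at 50 nM and 386 between the doses. Every other setting kept the number of changed genes within 1.5 times, except 3441 between the doses without the 50 nM replicate 1, whose cause was not tested. With 1 library left out at a time the counts ranged from 6834 to 7893, from 8331 to 8763 and from 3441 to 5829. In the same order they were 8352, 9547 and 5781 with limma-voom, 8439, 10114 and 5400 with the deposited log2 FPKM, 7569, 10155 and 4486 with no filter, and 7515, 8045 and 4995 with protein-coding genes only. Of the changed genes, 50.5%, 48.1% and 44.0% were higher, against 47.1%, 56.3% and 69.9% under scaling by fragment totals and 55.3%, 45.6% and 32.6% under upper quartile scaling. With protein-coding genes only, 47%, 39.4% and 36.2% were higher.

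Correlations between samples of the same replicate number ranged from -0.047 to 0.079, and those between other numbers from -0.11 to 0.06. They gave no sign of pairs, but with 3 libraries per group they cannot show that the numbers mark none. The replicate block gave 7640, 9107 and 4587 genes. The correlation of the 2 doses was 0.855 over genes with a mean of at least 5 CPM and 0.788 to 0.800 with 1 DMSO library left out. With an estimated correlation camera called 0 lists in each comparison, and fry called 33, 23 and 28 lists by direction and 36 in each comparison when members could move either way. Without mitochondrially encoded genes, the difference in the share of the 10 most abundant genes was 0.267 percentage points instead of 1.67 at 25 nM, -0.113 instead of 2.38 at 50 nM and -0.38 instead of 0.71 between the doses, since several of the 10 are mitochondrial.

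The named genes gave 540 results and 11310 comparisons with an alternative, of which 10756 kept direction and call, 524 kept direction without the call and 30 gained a call. Of the 524, 416 came from requiring a log2 fold change of at least 1. The lists gave 106 results and 1166 comparisons, of which 995 were the same, 84 weaker and 87 stronger. The estimated correlation gave 60 of the weaker ones. Of the stronger ones, fry gave 28 by direction and 46 when members could move either way. Median-of-ratios scaling, which moved nothing, gave 540 of the unchanged gene comparisons and 106 of the unchanged list comparisons. Depth limits genes near 0.5 FPKM, where a single fragment on a 1 kb gene equals 0.0343 to 0.0415 FPKM. On a shorter gene, such as a small RNA gene, a single fragment is worth more.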

Other observations

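The tests of depth and of S phase, and RN7SK as an example, were chosen only after the result was seen.

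Among histones, HIST1H1E rose by 2.84 at 25 nM and 3.87 at 50 nM on the log2 scale (limma adjusted p = 1.55e-06 at 50 nM), and HIST1H4E rose by 1.86 and 1.99. Replication-dependent histone messenger RNAs end in a stem-loop without a poly(A) tail, and near-identical copies share reads, so single histone values are uncertain. The abundant non-coding RNA RN7SK, named after its values were seen, likewise has no tail and went from 5.61 to 29.0 FPKM between DMSO and 50 nM, a log2 fold change of 2.34 (SE 0.18, limma adjusted p = 1.14e-05).

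Of 13 tested histone genes 7 were higher and 1 lower at 50 nM, and the list was not called (camera adjusted p = 0.0525 by limma, adjusted p = 0.704 with an estimated correlation). The higher values may come in part from more RNA without poly(A) tails in these libraries. The 45 tested genes taken to stand for RNAs without tails had a median log2 fold change of 1.242 (95% bootstrap interval 0.831 to 1.526). Of these, 22 were higher and 2 lower, and the histone median was 0.482. Most carry names of pseudogene copies of small nuclear RNA genes, where reads need not come from RNA without tails. Their median therefore cannot tell whether the 50 nM libraries hold more such RNA. It was 0.83 in the 19 inside coding genes, 1.33 in 18 elsewhere and 2.11 in 8 whose place is not given. A larger share of cells in S phase was not settled: the mean log2 fold change of the DNA replication list was -0.042 (SE 0.042), with 8 members higher and 13 lower.

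The 2-fold rise of 789 non-coding genes at 50 nM could reflect unspliced RNA of the coding genes around them. Of 858 non-coding genes inside a coding gene or within 10 kb downstream on the same strand, 345 were 2-fold higher, against 102 of 699 more than 10 kb from any coding gene (odds ratio 3.93, 95% interval 3.05 to 5.11, Fisher's exact p = 7.14e-30). The share was 48.4% of 506 genes inside a coding gene on the same strand, 28.4% of 352 genes downstream, 25.8% of 1322 genes in other places near coding genes and 14.6% of the far genes, so read-through downstream of coding genes stays open. Genomic DNA was excluded as the main source, since 496 silent receptor and keratin-associated genes gained 0.207% of the median gain of the non-coding genes (upper bound 0.468%). Greater depth was excluded as well, with a difference of -2.6 M fragments between 50 nM and DMSO. The far genes had a median log2 fold change of 0.27, and read-through over longer distances was not tested.

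Of 19 heat shock genes, 10 stood lower at 50 nM than at 25 nM, DNAJB1 by -0.98 and HSPA8 by -0.45 on the log2 scale, and 9 were not called. The camera call of the list was lost with an estimated correlation (camera adjusted p = 0.193). Of the 10 members called lower, at least 9 stayed lower under each of 3 other scalings, and 9 stayed lower without the 25 nM replicate 3, so neither scaling nor that library accounts for the difference. A weaker or more advanced chaperone response at the higher dose remains a hypothesis, which a time course could test.

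Splits of the 6 libraries of a comparison into 3 and 3, 10 in all with the true grouping among them, are too few for a share under 0.05. At 25 nM against DMSO the true grouping gave 8086 genes and the highest other split 2, so only the true grouping, 1 of 10 splits, reached its count. At 50 nM against DMSO the counts were 9441 and 1, and between the doses 5205 and 1, again reached by the true grouping alone.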
